A study of Arabidopsis thaliana and Brassica rapa with 28 samples.

How the data were processed

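Transcript levels were measured by RNA sequencing in 28 samples forming 8 groups: 16 Arabidopsis libraries, 4 per group, and 12 Brassica rapa libraries, 3 per group. Per the labels, polyadenylated RNA was made into stranded libraries and sequenced as single-end reads of 50 bp. The authors called bases with CASAVA 1.8.2, aligned reads with TopHat2 2.0.9 and Bowtie2 2.1.0, and estimated and compared transcript levels with Cufflinks and Cuffdiff, whose versions were not given in the sources used here. The genome build is given as TAIR10 for every sample. The Brassica build is not given in the sources used here, although the Brassica tables carry Brara identifiers.

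The 14 gene tables each compare a pair of groups: 6 for Arabidopsis, 4 for Brassica, and the same 4 Brassica pairs with the authors' correction for multiply mapped reads. FPKM values (fragments scaled to gene length and library size) were computed by the authors with Cuffdiff, which pools the libraries of a group into 1 value. The score of each gene is the test statistic that the authors' Cuffdiff run deposited for the pair of groups. The p-value and q-value of each gene are those the authors deposited, and q differs from a Benjamini-Hochberg adjustment over 1 table alone. The smallest p in the tables was 5e-05. Values per library are not in the tables, so the depth per sample is unknown and no precision from depth can be stated.

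A gene counted as called at a q under 0.05 among the genes the authors marked as tested. Log2 folds were computed here as the ratio of the group FPKMs without a pseudocount, because some cells of the deposited fold column held a spreadsheet error in place of a number and others differed from the FPKM ratio. The standard error of a log2 fold was its size divided by the authors' statistic, times the median ratio of the statistic to the normal deviate of p, taken over genes with p from 0.001 to 0.5. This factor was 0.558 to 0.564 in the Arabidopsis and 0.670 to 0.762 in the Brassica tables. Among genes above the smallest p, the statistic was more than 2 times larger than this factor gives in 1.55 to 1.76% of Arabidopsis and 7.58 to 9.75% of Brassica genes, which makes their standard errors too small.

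The 10 main comparisons were the 6 pairs of Arabidopsis groups, shade against W in each Brassica tissue, and peels against whole hypocotyls in each light. Differences between the shade responses of the genotypes, and of the Brassica tissues, were tested per gene with a two-sided z test on the log2 folds and their standard errors, for genes with an FPKM of at least 1 in a group, with Benjamini-Hochberg adjustment. Overlaps of called genes were tested with the two-sided Fisher exact test over genes tested in both comparisons, and Spearman's rho was taken over genes. Overlaps, correlations and difference tests were computed only between comparisons sharing no library.

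The 22 gene lists, with 336 members and 332 distinct genes, were written from general knowledge before the data were examined, as were the groups, comparisons, tests, thresholds, rule for naming genes and the alternatives not described otherwise. They cover auxin early response, SAUR genes, auxin synthesis and transport, auxin perception, shade markers, brassinosteroid synthesis and inactivation, brassinosteroid signalling and response, cell wall expansion, gibberellin, cytokinin response, ethylene, abscisic acid response, wound, jasmonate and touch, salicylate defence, the clock, flavonoids, the epidermis and cuticle, stomata, vascular tissue, the endodermis, photosynthesis and the cell cycle. ACS4 and ACS8 are in the auxin early-response and ethylene lists. TCH4 is in the brassinosteroid response and cell wall lists, and XTH15 in the shade marker and cell wall lists. Each counts in both of its lists, so results of these lists are not separate. All 332 loci were found in the reference annotation. For each Arabidopsis comparison a two-sided Fisher exact test compared called members with all other tested genes, separately for higher and lower, adjusted over the 44 tests of that comparison. Counts adjusted over the list alone use the Benjamini-Hochberg method on the authors' p of the tested members. Mean differences of the log2 folds of a list were tested by flipping signs over genes, exactly for small lists and with 100000 resamples otherwise, adjusted over the lists; this test of lists was chosen after seeing the data. Where the median of a list is set beside random lists, 10000 lists matched over 20 bins of expression were drawn. Intervals of ratios and correlations were taken from 500 bootstrap draws over genes, also chosen after seeing the data.

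Genes were named by a rule: 12 key genes in every Arabidopsis comparison; from each list with a called gene up to 4 called members with the largest size of log2 fold and an FPKM of at least 1 in a group; the 5 largest rises and falls among called genes with an FPKM of at least 1 in both groups and a symbol; and the 10 genes with the smallest adjusted p and a symbol in the difference tests. Brassica identifiers named in the report, and the genes named as shared between comparisons, were picked after their values were seen.

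The alternatives were a q under 0.01, a log2 fold limit of 1, an FPKM minimum of 1 or 5 or none, adjustment over 1 table alone, log2 folds centred on their median, pseudocounts of 1 and 0.1, the Brassica tables with multi-read correction, and standard errors from p alone or from the unscaled statistic. Uncentred z values, and standard errors from p wherever it was above its smallest value and from the scaled statistic elsewhere, were chosen after seeing the data. So were 3 further gene lists used only in the closing section.

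The difference test was tested on simulated data with 200 changed genes, 100 of each size. In the Arabidopsis setting it recovered 27 of those changed by 1 and 70 of those changed by 2 on the log2 scale, with 6 unchanged genes past the threshold. With too large a statistic in the real share of genes it recovered 19 and 74, with 8 unchanged genes. In the Brassica setting it recovered 28 and 81, with 5 unchanged genes, and with too large a statistic 36 and 86, with 160 unchanged genes, or 21 with the standard error taken from p where possible. The too large statistic was 5 times the true one in both settings, in genes drawn separately for each comparison. Some uncalled genes in the data went beyond this, such as TRNP at 1.65 ± 0.035 in control shade. Of the 124 Arabidopsis genes that passed in the data, 78 were called in neither shade comparison. The simulated numbers of unchanged genes can thus be too low. In 200 runs of random calls 4 had a list past 0.05, and a list with 5 called members was recovered in 200 of 200 runs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The gene lists were not applied to Brassica, as no map between Brara identifiers and Arabidopsis genes was available.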

Results

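The series compared transcript levels in seedlings of Arabidopsis thaliana and Brassica rapa kept in white light (W) or moved to shade, which here means light with a low ratio of red to far-red. The 16 Arabidopsis libraries came from whole 5-d-old seedlings, with 4 libraries in each of 4 groups: control or CER6pro>>axr3-1 seedlings after 4 h of W or of shade. The axr3-1 allele encodes a stabilised form of AXR3 (also named IAA17), a repressor of auxin response, here fused to the fluorescent protein mCit, and the promoter of the wax synthesis gene CER6 is active in the epidermis. Control seedlings carried the UAS::axr3-1::mCit construct in the hemizygous state. The 12 Brassica libraries came from 4-d-old plants of the FPsc strain after 9 h of W or of shade, with 3 libraries in each of 4 groups: whole hypocotyls or peels of the hypocotyl epidermis in either light. Polyadenylated RNA was sequenced as stranded libraries. Each gene had 1 FPKM per group, pooled over its libraries by the authors, so the depth per library is unknown and no spread between libraries could be computed here. From 19982 to 20097 genes had an FPKM of at least 1 in the Arabidopsis groups, and from 28149 to 29765 genes did in the Brassica groups. The 10 most abundant genes held 11.01 to 14.98% of the summed FPKM in the Arabidopsis groups and 24.6 to 39.0% in the Brassica groups. A gene is called higher or lower below where its q in the authors' deposited table was under 0.05. Log2 folds are given with the standard error (±) obtained from the authors' test statistic. The labels do not say whether the libraries of a group came from separate plant cultures, so these p-values measure only the spread between these libraries.

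AXR3, whose sequence the transgene carries, was higher in CER6pro>>axr3-1 seedlings in both lights. AXR3 (AT1G04250), on chromosome 1 from 1136258 to 1138613 of TAIR10, had a group FPKM of 47.1 in control and 113 in CER6pro>>axr3-1 seedlings in W. In shade its FPKM was 37.1 in control and 112 in CER6pro>>axr3-1 seedlings. The log2 folds between the genotypes were 1.26 ± 0.20 in W and 1.59 ± 0.21 in shade, and the authors' deposited table gives q = 0.00309 for each. AXR3 was not called between shade and W in either genotype, with log2 folds of -0.34 ± 0.20 in control and -0.01 ± 0.21 in CER6pro>>axr3-1 seedlings. CER6 (AT1G68530), the gene whose promoter drove the transgene, was not called in any of these 4 comparisons, and its log2 fold between the genotypes was -0.55 ± 0.29 in W and 0.02 ± 0.30 in shade. Reads of the endogenous gene and of the transgene cannot be separated in these values.

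The comparison of shade with W in control seedlings asked which transcripts respond to 4 h of shade. Transcripts of 8 of 14 shade markers and 10 of 20 auxin early-response genes rose, and those of 8 of 12 flavonoid genes fell. PIL1 (AT2G46970) rose from 0.894 to 37.3 FPKM, a log2 fold of 5.38 ± 0.34, and HFR1 (AT1G02340) rose by 3.86 ± 0.23; both encode bHLH proteins of the shade response. XTH15 (AT4G14130), which encodes a cell wall xyloglucan-modifying enzyme, rose by 5.03 ± 0.24, and the homeobox gene ATHB2 (AT4G16780) rose by 3.07 ± 0.20. The anthocyanin synthesis genes DFR (AT5G42800) and LDOX (AT4G22880) changed by -4.30 ± 0.30 and -3.64 ± 0.36 on the log2 scale. In all, 580 of 20325 tested genes were called, 253 higher and 327 lower, and the authors' deposited table gives its smallest q, 0.00309, for the 6 genes just named.

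Among shade markers 8 of 14 rose and 0 fell in control seedlings (Fisher exact test, adjusted p = 2.83e-11), and 11 rose when adjusted over the list alone. Of the auxin early-response genes 10 of 20 rose, 14 when adjusted over the list alone (Fisher exact test, adjusted p = 5.45e-13). They included the ethylene precursor synthesis gene ACS8 (AT4G37770) at 5.03 ± 0.36, the auxin response repressor genes IAA29 (AT4G32280) at 4.29 ± 0.36 and IAA19 (AT3G15540) at 2.04 ± 0.26, and the auxin-conjugating enzyme gene GH3.3 (AT2G23170) at 1.81 ± 0.22. In the auxin synthesis and transport list 4 of 19 rose, and 6 rose and 1 fell when adjusted over the list alone (Fisher exact test, adjusted p = 5.75e-04). These were the YUC flavin monooxygenase genes YUC8 (AT4G28720) at 3.24 ± 0.30, YUC2 (AT4G13260) at 1.62 ± 0.36 and YUC9 (AT1G04180), from 2.02 to 4.97 FPKM, and the auxin efflux carrier gene PIN3 (AT1G70940) at 1.01 ± 0.27. Of the SAUR genes, small auxin-induced transcripts, 2 of 25 rose and 1 fell (adjusted over the list alone, 6 rose and 1 fell), and their Fisher exact test did not pass (adjusted p = 0.153).

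Brassinosteroid signalling and response genes rose in 3 of 17 cases in control shade, 5 when adjusted over the list alone (Fisher exact test, adjusted p = 0.00626). These were the bHLH genes BEE1 (AT1G18400) at 2.86 ± 0.24 and PRE6 (AT1G26945) at 1.95 ± 0.16 and the xyloglucan-modifying enzyme gene TCH4 (AT5G57560) at 1.51 ± 0.21. The brassinosteroid synthesis genes DWF4 (AT3G50660) and CPD (AT5G05690) had log2 folds of -0.58 ± 0.21 and 0.65 ± 0.26 and were not called. Of the cell wall genes 7 of 23 rose and 2 fell, with 8 and 2 when adjusted over the list alone (Fisher exact test for the rise, adjusted p = 9.70e-08). XTH33 (AT1G10550) rose by 2.87 ± 0.39. The cell wall count also includes TCH4 and the shade marker XTH15, which were counted in other lists above. In the gibberellin list 5 of 20 rose and 1 fell, with 7 and 1 when adjusted over the list alone (Fisher exact test for the rise, adjusted p = 3.36e-05). The synthesis gene GA20OX3 (AT5G07200) rose by 2.06 ± 0.50, the inactivation gene GA2OX6 (AT1G02400) rose by 1.86 ± 0.29, and the synthesis gene GA3OX2 (AT1G80340) changed by -1.56 ± 0.37. Ethylene genes rose in 2 of 6 cases, 3 when adjusted over the list alone (Fisher exact test, adjusted p = 0.0110). The 2 were ACS4 and ACS8, which the auxin early-response list also counts, here and in the comparisons below. The 2 abscisic acid response genes of 10 that rose (3 when adjusted over the list alone) were COR15A (AT2G42540) at 4.48 ± 0.35 and RD29A (AT5G52310) at 3.28 ± 0.28, which also respond to cold (Fisher exact test, adjusted p = 0.0286).

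Flavonoid genes fell in 8 of 12 cases in control shade, 10 when adjusted over the list alone (Fisher exact test, adjusted p = 2.83e-11), among them the anthocyanin glycosylation gene UF3GT (AT5G54060) at -3.58 ± 0.43. Wound, jasmonate and touch genes fell in 4 of 22 cases, 6 when adjusted over the list alone (Fisher exact test, adjusted p = 0.00241), with the lipoxygenase gene LOX3 (AT1G17420) at -1.68 ± 0.34 and the storage protein gene VSP2 (AT5G24770) at -1.42 ± 0.32. Fewer members passed in 3 other lists, where the Fisher exact test did not pass: 1 of 7 cytokinin response genes, 1 of 26 epidermis and cuticle genes and 1 of 22 photosynthesis genes fell (2, 4 and 1 when adjusted over the list alone). Cuffdiff called 0 members in 8 lists. Their members at an unadjusted p under 0.05 were 3 of 13 for brassinosteroid synthesis and inactivation, 2 of 10 for the clock, 2 of 9 for stomata, 1 of 11 for auxin perception, 1 of 21 for vascular tissue, 0 of 5 for salicylate defence, 0 of 2 for the endodermis and 0 of 7 for the cell cycle. Adjusted over the list alone, 2 brassinosteroid synthesis genes rose and 1 fell, and 2 clock genes rose. Log2 folds were below 0, mostly without a call, for 20 of 21 vascular markers (median -0.24; 0 called), 20 of 22 photosynthesis genes (median -0.25; 1 called) and 20 of 26 epidermis and cuticle genes (median -0.27; 1 called). At a q under 0.01 the tests of the gibberellin and ethylene lists no longer passed (Fisher exact test, adjusted p = 0.0709 and 0.199). The Fisher tests treat genes as independent.

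In CER6pro>>axr3-1 seedlings the same comparison of shade with W asked how seedlings with the epidermal repressor respond. Of the shade markers 9 of 14 rose, of the flavonoid genes 10 of 12 fell, and no SAUR gene was called higher. PIL1 rose from 0.895 to 44.6 FPKM, a log2 fold of 5.64 ± 0.33, HFR1 rose by 3.90 ± 0.22 and ATHB2 by 3.73 ± 0.21. FLP1 (AT4G31380) had the largest rise among called genes with a symbol and an FPKM of at least 1 in both groups, at 5.67 ± 0.37. UF3GT, DFR and LDOX changed by -3.54 ± 0.37, -3.53 ± 0.25 and -3.32 ± 0.31. Cuffdiff called 516 of 20441 tested genes, 159 higher and 357 lower, and q was 0.00309 in the authors' deposited table for each of these 7 genes.

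Shade markers rose in 9 of 14 cases in CER6pro>>axr3-1 seedlings, 10 when adjusted over the list alone (Fisher exact test, adjusted p = 3.53e-15). Auxin early-response genes rose in 8 of 19 cases and fell in 1, with the same numbers when adjusted over the list alone (Fisher exact test for the rise, adjusted p = 1.16e-11). IAA29 rose by 3.79 ± 0.36, ACS8 by 3.56 ± 0.28, IAA19 by 1.59 ± 0.23 and GH3.3 by 1.09 ± 0.25, while the ethylene precursor synthesis gene ACS4 (AT2G22810) fell from 16.2 to 8.07 FPKM. Of the SAUR genes 0 rose and 1 of 24 fell, SAUR14 (AT4G38840) at -1.52 ± 0.18; by Cuffdiff, 4 were at an unadjusted p under 0.05, and 2 rose when adjusted over the list alone. In the auxin synthesis and transport list 5 of 19 rose and 1 fell, with 6 and 1 when adjusted over the list alone (Fisher exact test for the rise, adjusted p = 2.51e-06). YUC9 rose by 3.61 ± 0.32, YUC8 by 1.75 ± 0.25 and YUC5 (AT5G43890) by 1.41 ± 0.29, whereas TAA1 (AT1G70560), whose enzyme makes the precursor that YUC enzymes use, changed by -1.32 ± 0.23.

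Brassinosteroid synthesis and inactivation genes rose in 2 of 13 cases in CER6pro>>axr3-1 shade, also when adjusted over the list alone (Fisher exact test, adjusted p = 0.0217). They were the synthesis genes CPD at 1.13 ± 0.27 and BR6OX2 (AT3G30180) at 0.92 ± 0.20. PRE6 and BEE1 rose by 1.17 ± 0.14 and 0.85 ± 0.18, 2 of 17 in the brassinosteroid response list and 4 when adjusted over the list alone (Fisher exact test, adjusted p = 0.0333). Cell wall genes rose in 4 of 23 cases and fell in 1, with 5 and 2 when adjusted over the list alone (Fisher exact test for the rise, adjusted p = 2.04e-04), XTH15 by 4.52 ± 0.26. GA20OX3 and GA2OX6 rose by 2.25 ± 0.52 and 1.13 ± 0.30, 2 of 20 gibberellin genes, and 2 rose and 1 fell when adjusted over the list alone (Fisher exact test, adjusted p = 0.0417). Of the type-A response regulator genes induced by cytokinin, 2 of 6 fell, 4 when adjusted over the list alone (Fisher exact test, adjusted p = 0.0217), ARR6 (AT5G62920) at -1.05 ± 0.22 and ARR4 (AT1G10470) at -0.98 ± 0.20. Abscisic acid response genes went both ways: COR15A and RD29A rose by 2.08 ± 0.38 and 1.65 ± 0.32, and RD29B (AT5G52300) and KIN1 (AT5G15960) changed by -1.08 ± 0.44 and -1.07 ± 0.20. Of the 10, 2 rose and 3 fell when adjusted over the list alone (Fisher exact test, adjusted p = 0.0163 for the rise and 0.0457 for the fall).

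Flavonoid genes fell in 10 of 12 cases in CER6pro>>axr3-1 shade, also when adjusted over the list alone (Fisher exact test, adjusted p = 3.53e-15), including MYB75 (AT1G56650), a transcription factor gene of anthocyanin synthesis, at -3.90 ± 0.47. Wound, jasmonate and touch genes fell in 7 of 23 cases, 10 when adjusted over the list alone (Fisher exact test, adjusted p = 9.91e-07), with the jasmonate synthesis gene AOC1 (AT3G25760) at -1.56 ± 0.20. Among ethylene genes 1 of 7 rose and 1 fell, and among stomatal genes 1 of 9 rose, the guard cell potassium channel gene KAT1 (AT5G46240) at 1.98 ± 0.31; the numbers were the same when adjusted over the list alone, and neither Fisher exact test passed. In another 8 lists Cuffdiff called 0 members. Those at an unadjusted p under 0.05 were 3 of 10 for the clock, 2 of 26 for the epidermis and cuticle, 1 of 22 for photosynthesis, and 0 of 11 for auxin perception, 0 of 5 for salicylate defence, 0 of 21 for vascular tissue, 0 of 2 for the endodermis and 0 of 7 for the cell cycle. Adjusted over the list alone 2 clock genes rose. Log2 folds were below 0, none of them with a call, for 21 of 22 photosynthesis genes (median -0.28) and 18 of 21 vascular markers (median -0.18). At a q under 0.01 the tests of the brassinosteroid response, gibberellin and cytokinin lists and of the fall in the abscisic acid list no longer passed (Fisher exact test, adjusted p = 0.292, 0.316, 0.245 and 1). With z recomputed from the authors' statistic RD29B was not called.

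Setting the shade responses of the genotypes side by side addresses whether repression in the epidermis changed the response. SAUR, auxin early-response, gibberellin, abscisic acid and wound genes had lower mean log2 folds in CER6pro>>axr3-1 seedlings, and shade markers went both ways. The SAUR and auxin early-response genes started from a higher level in CER6pro>>axr3-1 seedlings in W, where their median log2 folds over control were 0.86 (23 of 24 above 0) and 0.74 (16 of 19). In shade these medians were 0.45 (20 of 25) and 0.34 (13 of 20). A higher level in W lowers the difference of the shade folds by arithmetic, and a lower one raises it. The same holds for the other lists here. In W the medians over control were -0.44 for epidermis and cuticle genes (24 of 26 below 0), 0.25 for wound genes (19 of 23 above 0), 0.17 for gibberellin genes (13 of 19) and 0.27 for abscisic acid genes (7 of 10). In shade they were -0.29, 0.12, 0.02 and -0.33. For the abscisic acid genes the mean log2 fold over control was 0.18 in W and -0.76 in shade. By these means the larger part of the difference for that list arose in shade. The shade mean rests heavily on COR15A, RD29A and KIN1, at -3.09, -1.94 and -1.33. The medians, 0.27 in W and -0.33 in shade, were of similar size, so the level in W also matters for this list. Mean differences in log2 fold (CER6pro>>axr3-1 minus control) were -0.75 over 24 SAUR genes, 21 of them lower, and -0.49 over 19 auxin early-response genes, 16 of them lower (sign-flip permutation tests over genes, adjusted p = 0.00242 and 0.0279). The mean was -0.94 over 10 abscisic acid response genes, all 10 lower, -0.29 over 20 gibberellin genes, 16 lower, and -0.22 over 22 wound, jasmonate and touch genes, 17 lower (permutation tests, adjusted p = 0.0161, 0.0223 and 0.0161). Epidermis and cuticle genes had a mean difference of 0.17, higher in 20 of 26 (permutation test, adjusted p = 0.0411), and the 14 shade markers one of 0.05, from -0.68 for PIF6 (AT3G62090) to 0.66 for ATHB2 (permutation test, adjusted p = 0.764). By the z test per gene on the authors' statistics, members that differed numbered 3 for abscisic acid, 2 for SAUR, 1 for auxin early response and 0 each for gibberellin, wound, epidermis and shade markers. The other 15 lists did not pass, with adjusted p from 0.0982 to 1 (exact or permutation tests). With 5 salicylate and 2 endodermis genes the exact test could not give a p under 0.05. All 6 cytokinin response genes had the lower fold, with a mean difference of -0.42. Their p was the smallest that 6 genes can give (exact sign-flip test, p = 0.03125). The mean and the median differed in sign for brassinosteroid response genes (-0.26 and 0.01) and flavonoid genes (-0.01 and 0.29). The test of lists was chosen after seeing the data. It flips signs over genes, treats genes as independent and does not cover the spread between libraries, and several SAUR genes are near-identical copies, so their reads are hard to assign.

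Single genes whose shade responses differed included MLP28 (AT1G70830), which encodes an MLP-like protein, with log2 folds of -1.64 ± 0.27 in control and 2.21 ± 0.41 in CER6pro>>axr3-1 seedlings (z test of the difference on the authors' statistics, adjusted p = 3.78e-12). CYP79F1 (AT1G16410) of glucosinolate synthesis fell in control seedlings only, with log2 folds of -3.03 ± 0.26 in control and -0.42 ± 0.33 in CER6pro>>axr3-1 seedlings. YUC9 rose more in CER6pro>>axr3-1 seedlings. In control seedlings YUC9 went from 2.02 to 4.97 FPKM. Within CER6pro>>axr3-1 seedlings it rose by a log2 fold of 3.61 ± 0.32, reaching 37.9 FPKM in shade. YUC8 rose less, 3.24 ± 0.30 in control and 1.75 ± 0.25 in CER6pro>>axr3-1 seedlings. ACS4 went opposite ways, from 1.33 to 3.54 FPKM in control and from 16.2 to 8.07 in CER6pro>>axr3-1 seedlings. BEE1 rose by 2.86 ± 0.24 in control and 0.85 ± 0.18 in CER6pro>>axr3-1 seedlings, and the dark-induced gene SEN1 (AT4G35770) by 4.38 ± 0.23 in control and 1.97 ± 0.28 in CER6pro>>axr3-1 seedlings. For 5 of these genes the genotypes were called different in W and not in shade in the authors' deposited table, so the genotypes differed mostly in W. The FPKMs of control and CER6pro>>axr3-1 seedlings were 2.52 and 8.47 in W and 23.8 and 28.6 in shade for YUC8, 4.65 and 20.1 in W and 33.8 and 36.2 in shade for BEE1, 56.6 and 8.96 in W and 6.95 and 6.68 in shade for CYP79F1, 34.2 and 271 in W and 711 and 1063 in shade for SEN1 and 228 and 6.84 in W and 73.1 and 31.7 in shade for MLP28. The test gave 124 of 19989 genes, 37 with a higher and 87 with a lower log2 fold in CER6pro>>axr3-1 seedlings, and 78 of the 124 were called in neither shade comparison in the authors' deposited table. With the standard error taken from p wherever p was above its smallest value, 23 of the 124 passed, including all the genes named in this paragraph but YUC8 (adjusted p = 0.0898 in that z test of the authors' values), and with p alone MLP28 and ACS4 passed. With unscaled statistics 45 genes passed.

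The called genes of the genotypes overlapped in shade. Of 252 genes called higher in control and 155 in CER6pro>>axr3-1 seedlings, 115 were called higher in both, against 1.95 expected for independent sets (Fisher exact test, p = 1.34e-195). Of 326 and 354 genes called lower, 184 were shared, against 5.75 expected (Fisher exact test, p = 1.48e-253), and 2 genes were called in opposite directions, the 2 being MLP28 and ACS4. Across 20060 genes, which are not independent replicates, Spearman's rho between the log2 folds was 0.552. The median ratio of the CER6pro>>axr3-1 to the control fold was 0.746 over genes called in control. That of the control to the CER6pro>>axr3-1 fold was 0.872 over genes called in CER6pro>>axr3-1 seedlings. Calling genes in 1 comparison inflates the fold of that comparison, so both ratios can lie below 1 even for equal responses. The same holds for such ratios below.

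**Figure D1:**
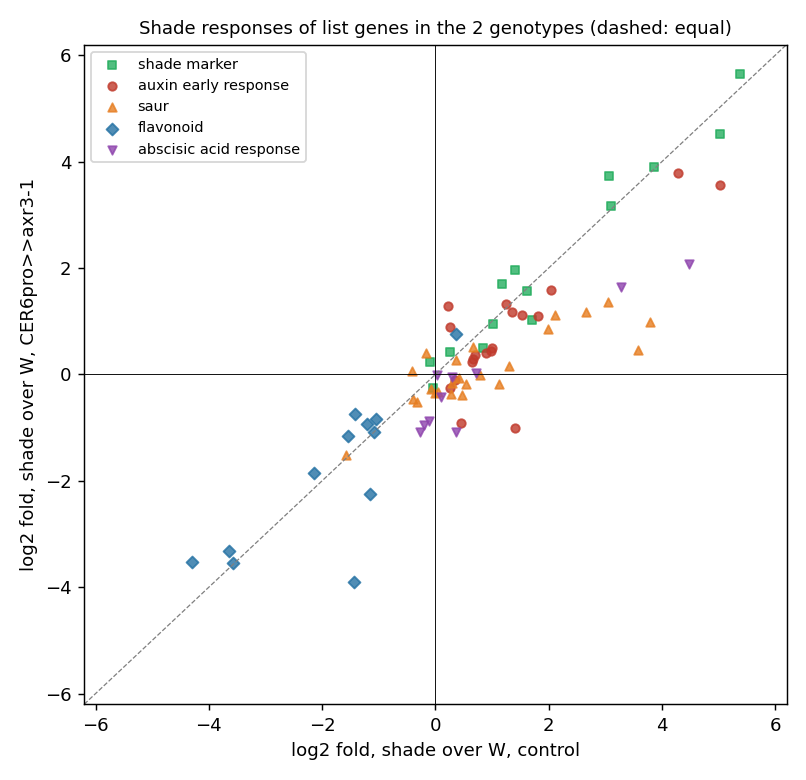
Log2 fold of shade over W in control seedlings (x axis) against that in CER6pro>>axr3-1 seedlings (y axis), from the authors' group FPKM, for genes of 5 lists, 1 point per gene and the dashed line where both are equal. SAUR and abscisic acid response genes lie mostly below the line (21 of 24 and 10 of 10), and shade markers lie around it, with 6 of 14 below.

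The comparison of CER6pro>>axr3-1 with control seedlings in W asked which transcripts differed between the genotypes without shade. Of the auxin early-response genes 9 of 19 were higher in CER6pro>>axr3-1 seedlings, and of the epidermis and cuticle genes 5 of 26 were lower. GH3.3 was at 15.5 FPKM in control and 73.1 in CER6pro>>axr3-1 seedlings, a log2 fold of 2.24 ± 0.22, and ACS4 was at 1.33 and 16.2 FPKM. PDF1 (AT2G42840), an epidermal marker, was at 411 and 202 FPKM (-1.03 ± 0.27). Among called genes with a symbol and an FPKM of at least 1 in both groups MLP28 had the largest fall, from 228 to 6.84 FPKM (-5.06 ± 0.32). Cuffdiff called 442 of 20470 tested genes, 299 higher and 143 lower, and the authors' deposited table gives q = 0.00309 for GH3.3, ACS4 and MLP28 and q = 0.00793 for PDF1.

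Auxin early-response genes were higher in 9 of 19 cases in W, 11 when adjusted over the list alone (Fisher exact test, adjusted p = 9.60e-11), among them IAA5 (AT1G15580) at 2.85 ± 0.38 and IAA19 at 1.56 ± 0.26. SAUR genes were higher in 5 of 24 cases, 13 higher and 1 lower when adjusted over the list alone (Fisher exact test, adjusted p = 1.92e-04), with SAUR15 (AT4G38850) at 2.34 ± 0.29 and SAUR9 (AT4G36110) at 2.17 ± 0.32. The 4 of 19 auxin synthesis and transport genes that were higher, also when adjusted over the list alone, were the synthesis genes YUC2 at 2.71 ± 0.34, YUC5 at 1.96 ± 0.39, YUC8 at 1.75 ± 0.32 and TAA1 at 1.68 ± 0.22 (Fisher exact test, adjusted p = 8.00e-04). Ethylene genes were higher in 3 of 7 cases, 4 when adjusted over the list alone (Fisher exact test, adjusted p = 7.58e-04). All 3 were ethylene precursor synthesis genes. ACS5 (AT5G65800) was at 0.174 FPKM in control and 4.29 in CER6pro>>axr3-1 seedlings. Its log2 fold of 4.63 ± 0.58 thus rests on a low control level. Gibberellin genes were higher in 4 of 19 cases, 5 when adjusted over the list alone (Fisher exact test, adjusted p = 8.00e-04), including the synthesis genes GA3OX1 (AT1G15550) at 1.44 ± 0.27 and GA20OX2 (AT5G51810) at 1.24 ± 0.27. BEE1 and PRE6 were higher by 2.11 ± 0.25 and 1.80 ± 0.16, 2 of 16 brassinosteroid response genes and 2 when adjusted over the list alone (Fisher exact test, adjusted p = 0.0981). The inactivation gene BAS1 (AT2G26710) was higher by 0.92 ± 0.27, 1 of 13 in its list and 1 when adjusted over the list alone (Fisher exact test, adjusted p = 0.589).

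Epidermis and cuticle genes were lower in 5 of 26 cases in W, 7 when adjusted over the list alone (Fisher exact test, adjusted p = 1.33e-05), and 24 of 26 had a log2 fold below 0 (median -0.44). The cutin and wax synthesis genes GPAT8 (AT4G00400) and KCS1 (AT1G01120) were at -0.91 ± 0.23 and -0.83 ± 0.21, and DCR (AT5G23940) at 40.8 FPKM in control and 20.4 in CER6pro>>axr3-1 seedlings. Cell wall genes split, 3 of 23 higher and 4 lower, with 4 and 5 when adjusted over the list alone (Fisher exact test, adjusted p = 0.0215 for higher and 1.92e-04 for lower). XTH24 (AT4G30270) and XTH19 (AT4G30290) were at 1.96 ± 0.22 and 1.58 ± 0.19, and XTH9 (AT4G03210) and the expansin gene EXPA8 (AT2G40610) at -1.07 ± 0.23 and -1.01 ± 0.22. Flavonoid genes were higher in 5 of 12 cases, 6 when adjusted over the list alone (Fisher exact test, adjusted p = 1.03e-05), with the regulator gene TT8 (AT4G09820) at 1.99 ± 0.38 and DFR at 0.93 ± 0.22. The vegetative storage protein genes VSP1 (AT5G24780) and VSP2 were higher by 3.36 ± 0.34 and 2.77 ± 0.28, 2 of 23 in the wound list and 5 when adjusted over the list alone (Fisher exact test, adjusted p = 0.161). PR5 (AT1G75040) of the salicylate list was at -1.69 ± 0.34, 1 of 5 and 1 when adjusted over the list alone (Fisher exact test, adjusted p = 0.138). Cuffdiff called 0 of 13 shade markers, with 2 at an unadjusted p under 0.05. It called 0 members of 9 further lists, where these numbers were 4 of 7 for the cell cycle, 3 of 10 for the clock, 2 of 10 for abscisic acid, 1 of 21 for vascular tissue, and 0 each for auxin perception, cytokinin, stomata, the endodermis and photosynthesis. Adjusted over the list alone, 2 abscisic acid genes and 1 clock gene were higher. All 7 cell cycle genes had log2 folds below 0 (median -0.47). At a q under 0.01 the tests of the gibberellin and ethylene lists and of the higher cell wall genes no longer passed (Fisher exact test, adjusted p = 0.0698, 0.227 and 0.0776).

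**Figure D2:**
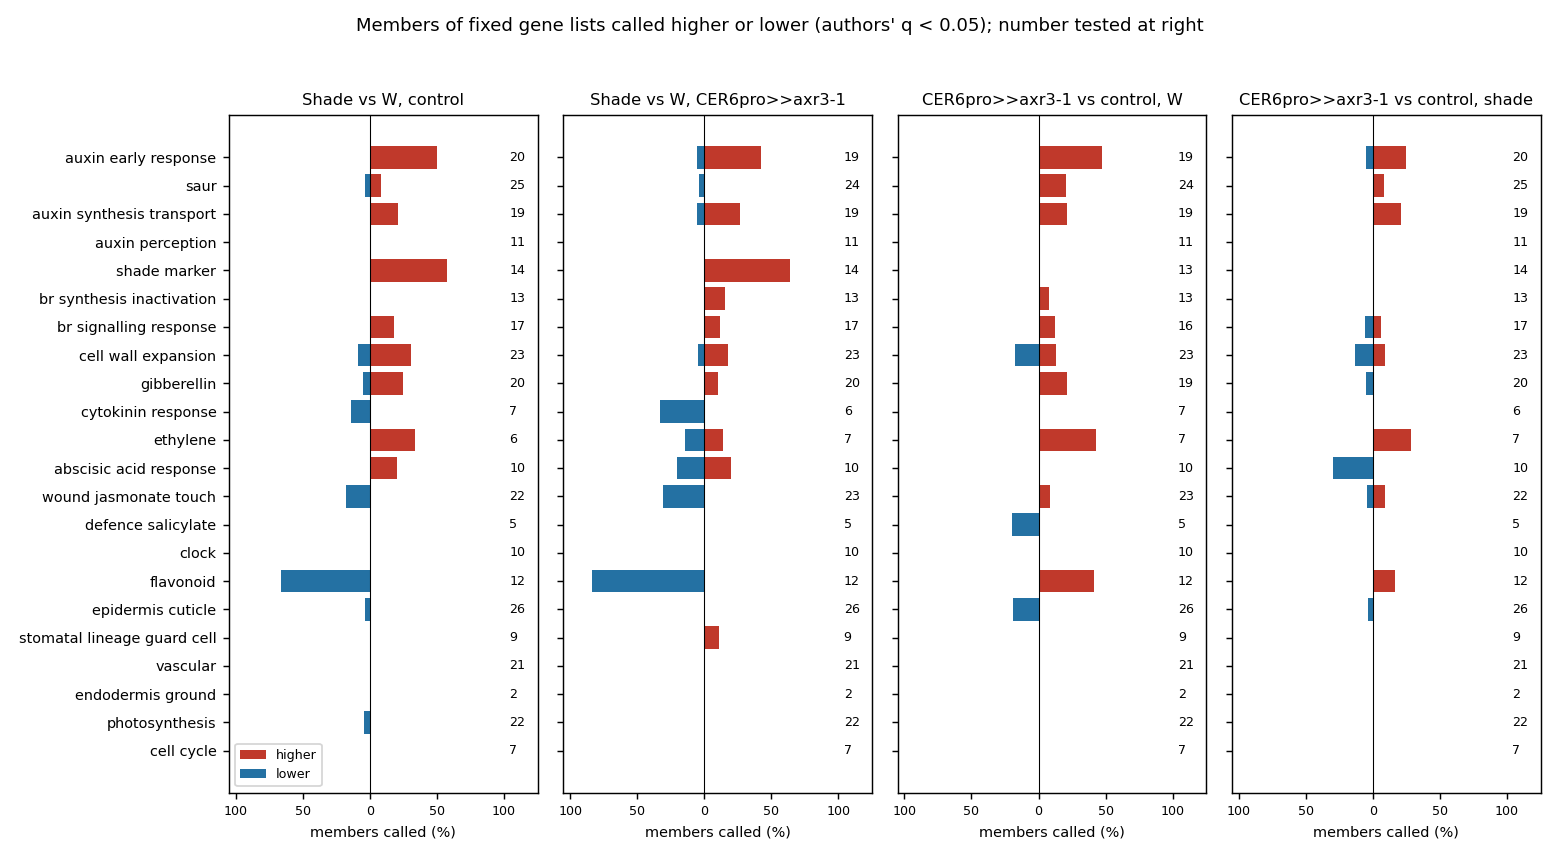
Percent of each list's tested members called higher (red, to the right) or lower (blue, to the left) at q under 0.05 in the authors' tables, for the 22 lists in 4 Arabidopsis comparisons; the numbers at the right are the members tested. Auxin early-response genes have 10 of 20, 8 of 19, 9 of 19 and 5 of 20 members higher, and flavonoid genes fall in shade in both genotypes (8 and 10 of 12).

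In shade, the comparison of CER6pro>>axr3-1 with control seedlings asked which genotype differences were present under shade. The auxin synthesis genes YUC2, YUC5 and YUC9 were higher in CER6pro>>axr3-1 seedlings, YUC8 was not called, and 3 of 10 abscisic acid response genes were lower. YUC5 was at 1.09 FPKM in control and 13.9 in CER6pro>>axr3-1 seedlings (3.67 ± 0.40), and YUC9 at 4.97 and 37.9 (2.93 ± 0.29). COR15A was at 306 and 35.9 FPKM (-3.09 ± 0.33), and COR15B (AT2G42530) and the galactinol synthase gene GolS3 (AT1G09350) at -2.55 ± 0.21 and -2.57 ± 0.27. Chosen in the same way, the largest rise was that of CYP82C4 (AT4G31940), induced by iron deficiency, at 4.59 ± 0.38. Cuffdiff called 255 of 20321 tested genes, 161 higher and 94 lower, and q was 0.00309 in the authors' deposited table for these 6 genes.

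Auxin synthesis and transport genes were higher in 4 of 19 cases in shade, also when adjusted over the list alone (Fisher exact test, adjusted p = 1.97e-04), with YUC2 at 1.59 ± 0.28 and TAA1 at 1.00 ± 0.25 beside YUC5 and YUC9. Auxin early-response genes were higher in 5 of 20 cases and lower in 1, with 7 and 2 when adjusted over the list alone (Fisher exact test for higher, adjusted p = 1.82e-05), with GH3.3 at 1.53 ± 0.24 and GH3.2 (AT4G37390) at 1.28 ± 0.24. The abscisic acid list was lower in 3 of 10 cases, also when adjusted over the list alone (Fisher exact test, adjusted p = 1.97e-04), with RD29A at -1.94 ± 0.33 and KIN1 at -1.33 ± 0.20. The 3 genes, RD29A, KIN1 and COR15A, are also in the cold-regulated list of the closing section. Cell wall genes were lower in 3 of 23 cases and higher in 2, with 7 and 3 when adjusted over the list alone (Fisher exact test for lower, adjusted p = 0.00175), with TCH4 at -0.87 ± 0.20, XTH9 at -0.86 ± 0.23 and XTH24 at 1.71 ± 0.24. ACS5 and ACS4 were higher by 2.06 ± 0.40 and 1.19 ± 0.33, 2 of 7 ethylene genes and 2 when adjusted over the list alone (Fisher exact test, adjusted p = 0.0112). DFR and TT7 (AT5G07990) were higher by 1.70 ± 0.32 and 1.02 ± 0.32, 2 of 12 flavonoid genes and 3 when adjusted over the list alone (Fisher exact test, adjusted p = 0.0287).

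No Fisher exact test passed for 5 lists with called members in shade: SAUR (2 of 25 higher), brassinosteroid response (1 of 17 higher and 1 lower), gibberellin (1 of 20 lower), wound (2 of 22 higher and 1 lower) and epidermis and cuticle (1 of 26 lower). Adjusted over the list alone these were 2, 1 and 1, 2 higher and 1 lower, 3 and 2, and 2. VSP2 and VSP1 were higher by 2.81 ± 0.37 and 2.56 ± 0.39, and the lipid transfer protein gene LTP2 (AT2G38530) was at -0.73 ± 0.17. Cuffdiff called 0 of 14 shade markers, with 1 at an unadjusted p under 0.05, and PIL1, HFR1 and ATHB2 had log2 folds of 0.26 ± 0.17, 0.03 ± 0.18 and 0.20 ± 0.17. By Cuffdiff 0 members of the remaining 10 lists were called, and the numbers at an unadjusted p under 0.05 were 3 for brassinosteroid synthesis and inactivation, 1 each for salicylate defence, the clock, stomata, photosynthesis and the cell cycle, and 0 for auxin perception, cytokinin, vascular tissue and the endodermis. Adjusted over the list alone, 1 salicylate defence gene was lower. Log2 folds were below 0 for all 7 cell cycle genes (median -0.38; 0 called) and 20 of 26 epidermis and cuticle genes (median -0.29; 1 called). At a q under 0.01 the ethylene and flavonoid tests no longer passed (Fisher exact test, adjusted p = 0.246 and 0.298). With the adjustment over all genes of this table only, SAUR15, GA2OX6, TT7 and LTP2 were not called, and with z recomputed from the authors' statistic GA2OX6 and TT7 were not.

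Genotype differences in W and in shade overlapped. Of 294 genes called higher in W and 159 in shade 112 were shared, against 2.33 expected (Fisher exact test, p = 3.75e-176), and of 142 and 92 called lower 35 were shared, against 0.65 expected (Fisher exact test, p = 1.22e-52). Cuffdiff calls of opposite direction numbered 0. YUC2, YUC5, TAA1, GH3.3 and IAA19 were among the shared higher genes, and COR15B among the shared lower genes. Across 20083 genes Spearman's rho was 0.516, and the median ratio of the shade to the W fold was 0.611 over genes called in W; the ratio of the W to the shade fold was 0.883 over genes called in shade.

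**Figure D3:**
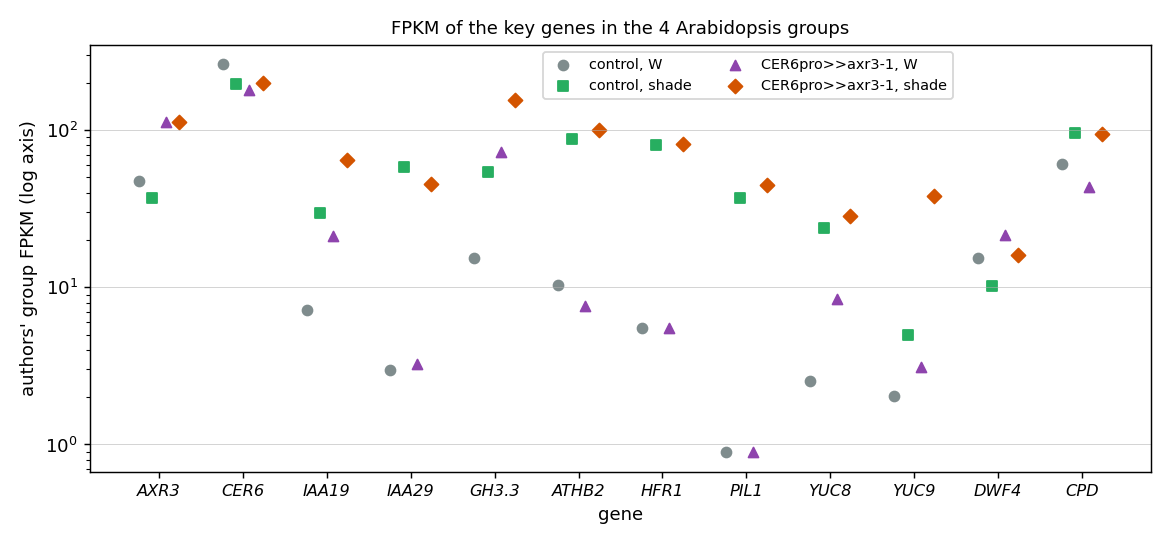
The authors' group FPKM (log axis) of 12 genes chosen before the data were examined, with 1 symbol for each of the 4 Arabidopsis groups and no error bars, since each group has 1 pooled value. AXR3 stands at 113 and 112 FPKM in CER6pro>>axr3-1 seedlings against 47.1 and 37.1 in control seedlings, while PIL1, HFR1 and ATHB2 follow the light in both genotypes.

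Both factors together gave the largest Arabidopsis counts. Between CER6pro>>axr3-1 seedlings in shade and control seedlings in W, 970 of 20423 tested genes were called, 508 higher and 462 lower: FLP1 was higher by 5.64 ± 0.37, PIL1 by 5.64 ± 0.34, SEN1 by 4.96 ± 0.26, IAA29 by 3.94 ± 0.37 and YUC9 by 4.23 ± 0.34. Auxin early-response genes were higher in 13 of 19 cases, 14 when adjusted over the list alone (Fisher exact test, adjusted p = 1.25e-15). Flavonoid genes were lower in 9 of 12, 9 when adjusted over the list alone (Fisher exact test, adjusted p = 6.55e-12). Between CER6pro>>axr3-1 seedlings in W and control seedlings in shade, 806 of 20458 genes were called, 559 higher and 247 lower. In that comparison the flavonoid genes DFR and LDOX were higher by 5.23 ± 0.30 and 4.36 ± 0.36, 10 of 12 of the list being higher and 10 when adjusted over the list alone (Fisher exact test, adjusted p = 2.96e-13). COR15B and COR15A were at -5.48 ± 0.31 and -5.17 ± 0.38, and DWF4 and CPD at 1.07 ± 0.21 and -1.14 ± 0.26, all 4 called. These comparisons change genotype and light at once and share libraries with those described before.

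The Brassica comparisons of shade with W asked how whole hypocotyls and the epidermis alone respond to 9 h of shade. Called genes were 37.6% of those tested in whole hypocotyls and 34.8% in peels. In whole hypocotyls 11511 of 30592 genes were called, 5381 higher and 6130 lower, and in epidermal peels 10624 of 30498, with 4937 higher and 5687 lower. The tables do not pair Brara identifiers with Arabidopsis genes, so the gene lists were not applied and genes are named by their own IDs. Brara.I00541 (A09, 3023978 to 3026038) rose in whole hypocotyls from 1.22 to 133 FPKM, a log2 fold of 6.76 ± 0.42, and in peels by 6.78 ± 0.43. Brara.H00699 (A08, 9079912 to 9081183) rose by 6.32 ± 0.39 in whole hypocotyls, where Brara.D00699 (A04, 5744124 to 5745868) and Brara.K01071 (Scaffold43463, 2163 to 4653) changed by -6.43 ± 0.30 and -6.40 ± 0.68. The authors' deposited table gives q = 0.000271 for each of these changes. With a limit of 1 on the size of the log2 fold, 5497 and 5818 genes were called in whole hypocotyls and peels.

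Shade responses of the Brassica tissues overlapped. Of 5260 genes called higher in whole hypocotyls and 4899 in peels, 3630 were shared, against 897.6 expected for independent sets, and of 5708 and 5272 called lower 3986 were shared, against 1048.2 expected; 67 and 52 genes were called in opposite directions. Brara.I00541 was among those called higher in both. Whole hypocotyls include the epidermis, so part of this overlap and of the correlation is built in. Across 28535 genes, which are not independent replicates, Spearman's rho was 0.779, and the median ratio of the peel to the whole-hypocotyl fold was 0.914 over genes called in whole hypocotyls. The ratio of the whole-hypocotyl to the peel fold was 0.861 over genes called in peels. A z test of the difference built on the authors' statistics gave 1917 of 28485 genes, 932 with the higher and 985 with the lower log2 fold in peels. This count fell to 689 with the standard error from p wherever p was above its smallest value, to 967 with unscaled statistics and to 253 with p alone.

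Comparing peels with whole hypocotyls asked which transcripts differ between the epidermis and the whole organ. In W 11857 of 31615 tested genes were called, 5845 higher and 6012 lower in peels, and in shade 10551 of 30463, 5077 higher and 5474 lower. In both lights 3712 genes were higher in peels and 3951 lower, against 913.6 and 1052.6 expected for independent sets, and 45 and 20 were called in opposite directions. Across 29289 genes Spearman's rho between the log2 folds in W and in shade was 0.829, with median ratios of 0.928 over genes called in W and 0.841 over genes called in shade. With a limit of 1 on the size of the log2 fold 6443 and 5978 genes were called. Peeling itself, beside the tissue, separates these groups.

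**Figure D4:**
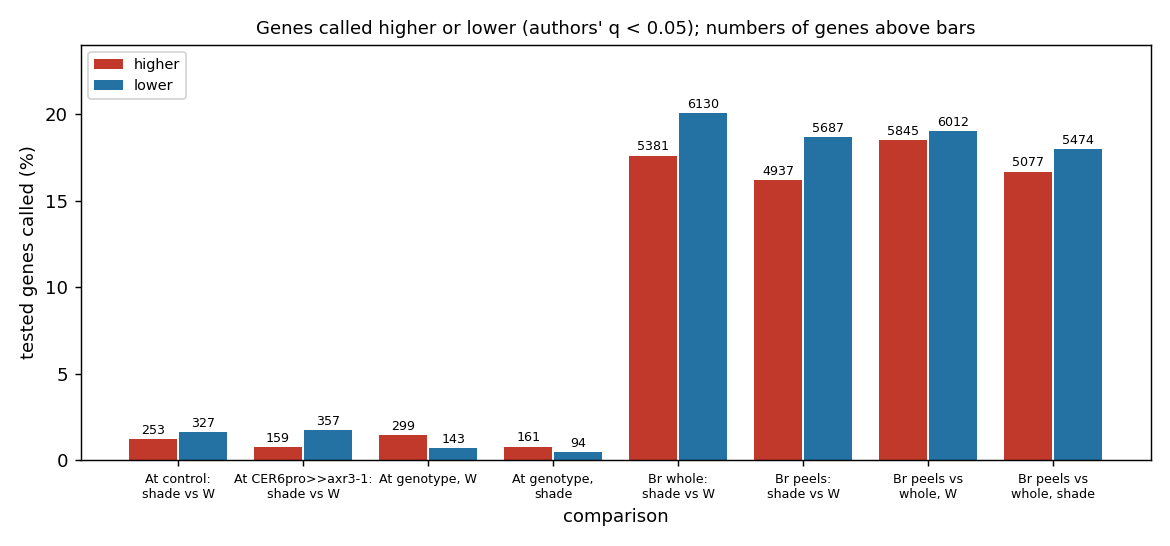
Percent of tested genes called higher (red) or lower (blue) at q under 0.05 in the authors' tables, for 8 comparisons within Arabidopsis (At) and Brassica (Br), with the number of genes above each bar. Called genes range from 94 lower in the Arabidopsis genotype comparison in shade to 6130 lower in Brassica whole hypocotyls in shade.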

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

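All tests of explanations in this part were chosen only after the results were seen, and so were the test of lists and the standard error taken from p where possible. The test per gene was set before the data were examined. Genes named here differed in their response to shade between CER6pro>>axr3-1 and control seedlings, and each value is the log2 fold in CER6pro>>axr3-1 seedlings minus that in control seedlings.

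YUC9 of auxin synthesis (2.32), CYP79F1 of glucosinolate synthesis (2.60) and MLP28 (3.85) had the higher fold in CER6pro>>axr3-1 seedlings. The fold was lower there for YUC8 (-1.49), the ethylene synthesis gene ACS4 (-2.42), SAUR10 (AT2G18010; -3.12), the bHLH genes BEE1 (-2.01) and PRE6 (-0.79), the cell wall gene TCH4 (-1.33), the anthocyanin regulator MYB75 (-2.46), the dark-induced SEN1 (-2.41) and the sulfotransferase gene ST2A (AT5G07010; -1.96). The cold-responsive genes COR15A (-2.39), RD29A (-1.63) and KIN1 (-1.44) had the lower fold as well. With the standard error from p where possible, PRE6 (z test of the authors' values, adjusted p = 0.125), YUC8, RD29A (adjusted p = 0.0866), KIN1 (adjusted p = 0.174), MYB75 and SAUR10 did not pass.

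Other entries were short or chloroplast transcripts or merged loci, none of them called in either shade comparison: TRNP (-2.88), TRNC (-1.44), TRNG.1 (-0.84) and YCF6 (-2.75) of the chloroplast, the RNAs U1.5 (AT1G08115; 0.54) and RSU1 (AT3G48130; -1.23), and AtRLP46 (2.66). They did not pass with the standard error from p where possible.

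By list, the mean difference was -0.75 for SAUR genes, -0.49 for auxin early-response genes, -0.94 for abscisic acid response genes, -0.29 for gibberellin genes, -0.22 for wound, jasmonate and touch genes and 0.17 for epidermis and cuticle genes. Levels in W enter each of these differences by arithmetic. For abscisic acid genes the mean log2 folds over control were 0.18 in W and -0.76 in shade, and the medians 0.27 and -0.33. The shade mean rests heavily on the members called lower there, COR15A, RD29A and KIN1. Per gene, the responses differed for 124 genes between the genotypes and for 1917 between Brassica peels and whole hypocotyls. These counts were 23 and 689 with the standard error from p where possible.

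In W, the auxin early-response and SAUR genes had a median log2 fold of CER6pro>>axr3-1 over control of 0.84 over 43 genes, with 39 above 0. The difference of shade folds uses the same W groups, so a higher level in W lowers it by arithmetic, and the lower shade folds are not separate evidence. The authors' scaling between groups is argued against, as the upper 95% bound for random lists was 0.0921. A lower share of epidermal RNA stays open for the epidermis and cuticle genes (median -0.44, 24 of 26 below 0, 5 called lower), but as the cause of the auxin and SAUR rise it is argued against, as it would raise the markers of other cell types alike, whose median was 0.0289 over 45 genes (two-sided permutation test of the difference, p = 1e-05, the smallest these permutations can give). Raised auxin synthesis stays open, with auxin itself not measured: 4 of 9 synthesis genes and 0 of 10 transport genes were called higher (by Cuffdiff 0 transport genes were at an unadjusted p under 0.05), but the list was split after the 4 were seen, so the Fisher exact test (p = 0.0325) restates that and supports nothing further.

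Of 13 cold-regulated genes, a list chosen after values were seen, 8 rose in control shade (median log2 fold 2.23) and 6 rose and 1 fell in CER6pro>>axr3-1 shade. COR15A, RD29A and KIN1 are also members of the abscisic acid list, so the results of these lists are not separate. An odd library in the control shade group is argued against as the cause of the rise, since the 6 genes called higher in CER6pro>>axr3-1 shade, all among the 8, come from other libraries and their q was adjusted over all genes, which the choice of the list does not change. The larger rise in control seedlings, with a median difference of -0.55 and 13 of 13 genes smaller in CER6pro>>axr3-1 seedlings, cannot be told apart from such a library, because values per library were not analysed here. Between the genotypes the list was lower in CER6pro>>axr3-1 seedlings in W, from libraries other than control shade (median -0.44, 10 of 12 below 0, 1 called lower), and in shade (median -1.33, 13 of 13 below 0, 8 called lower), though a lower level in W does not by itself give a smaller rise. Low red to far-red light is known to raise cold-regulated transcripts, and a difference in temperature between the lights was not tested.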

How the results depend on the processing

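Uncentred z values and the standard error from p where possible were chosen after seeing the data. Of the counts, correlations and ratios, 99 values stayed within their limits and 40 moved. Of single genes and lists, 1264 kept their side of the threshold, 106 were weaker and 0 reversed under the alternatives run. That 0 carries no information on direction. Only centring changed the fold of a gene, by 0.0041 to 0.0199 on the log2 scale, and list tests could not be labelled reversed. Over 185 pairs of a named gene and a comparison, those losing their call numbered 28 at a q under 0.01, 18 with the fold limit, 5 with adjustment over 1 table alone, and 4 each with centred and uncentred z. An FPKM minimum of 1 ended none. The rule that named list members and the largest rises and falls already required that FPKM. For those genes this result was fixed in advance and is no evidence of robustness. The rule also favoured large folds, which makes a loss of the call under the fold limit less likely. Over all genes that limit kept 385 of 580 calls in control shade. The 14 list tests that were lost were lost at a q under 0.01.

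At a q under 0.01 called genes numbered 322 for CER6pro>>axr3-1 shade, 266 and 157 for genotype in W and shade, and 622 for CER6pro>>axr3-1 shade against control W, with fewer genes by construction. With a log2 fold limit of 1 they were 385 in control shade, 516 for CER6pro>>axr3-1 W against control shade, 5497 and 5818 for Brassica shade in whole hypocotyls and peels, and 6443 and 5978 between tissues in W and shade. With z from the authors' statistic, centred and uncentred, they were 903 and 905 in control shade, 855 and 839 in CER6pro>>axr3-1 shade, 781 and 777 for genotype in W, 472 and 476 in shade, and, with both factors changed, 1634 and 1632, and 1327 and 1320. The cause was not tested.

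Differences between shade responses numbered 2, 45 and 23 for genotypes and 253, 967 and 689 for Brassica tissues, with standard errors from p alone, the unscaled statistic and p where possible. The first is limited by construction, since p has a smallest value. At a q under 0.01, shared genes were 199 for shade and 87 for genotype. Median ratios at that limit were 0.934 for control over CER6pro>>axr3-1 shade folds, 0.922 and 0.876 for Brassica shade and 0.854 for tissue. With a pseudocount of 1, rho was 0.572 for genotypes in shade, 0.789 for Brassica shade and 0.533 for genotype, and ratios were 0.851 for Brassica shade and 0.905 and 0.855 for tissue. The cause was not tested.

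No paired analysis was possible because the tables hold 1 pooled value per group. For the same reason the replicate block, leave-one-out and other splits of the libraries were not run, and what depth limits is unknown. The lists were not run with multi-read correction, as they were not applied to Brassica.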

Other observations

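The lists of iron-deficiency and aliphatic glucosinolate genes, and all tests of explanations in this part, were chosen only after values were seen. Of the iron-deficiency genes, 6 of 16 were called higher in CER6pro>>axr3-1 than in control seedlings in W and 7 of 16 in shade. No Fisher exact test was run on this list. Its median lay above the upper 95% bound of random lists, 0.154 in W and 0.123 in shade. As the list was chosen from these values, that adds no support. FRO2 (AT1G01580), which encodes a ferric chelate reductase of the root, had log2 folds of 5.15 in W and 3.57 in shade. The bHLH genes BHLH39 and BHLH101 of the same response had 4.16 and 3.36 in W and 3.88 and 3.43 in shade. The list medians, 2.41 in W (15 above 0) and 2.38 in shade (16 above 0), include genes that were not called. Among those not called in W were some of the largest folds, CYP82C4 at 8.23 ± 1.07, BHLH100 at 8.09 ± 1.47, BHLH38 at 5.52 ± 0.70 and IRT1 at 5.19 ± 0.94, with control FPKMs of 0.0438, 0.102, 0.331 and 1.42. No explanation was tested.

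Aliphatic glucosinolate genes, which make sulfur-rich defence compounds, were lower in control shade than in control W in 11 of 18 cases (median log2 fold -1.17), and lower in CER6pro>>axr3-1 W than in control W in 10 of 18 (median -1.13). The median over 17 of them was -0.22 in CER6pro>>axr3-1 shade against CER6pro>>axr3-1 W and -0.17 between the genotypes in shade. CYP79F1 had an FPKM of 56.6 in control W, 6.95 in control shade, 8.96 in CER6pro>>axr3-1 W and 6.68 in CER6pro>>axr3-1 shade. The first pair of comparisons shares the control W group, so a single high value there enters both, and values per library were not analysed here.

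Many more genes were called in Brassica than in Arabidopsis, 11511 in whole hypocotyls against 580 in control seedlings for shade. A smaller error per gene as the whole cause is argued against, since the share of tested genes that changed at least 2-fold, counting only those with an FPKM of at least 1, was 5.12 times as high (6982 of 30592, 22.8%, against 906 of 20325, 4.46%), with median standard errors of 0.221 and 0.264. The tables with multi-read correction called 11563 genes, 10623 of them shared with the tables without it, so the correction changed the count little. Whether it resolves reads of near-identical copies is not known here, so reads shared between paralogs stay open as a cause. Tissue, age, hours of light treatment and species differ together between the sets, so no biological explanation was tested.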
